A study of Mus musculus with 40 samples.

How the data were processed

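RNA from mouse placentas at embryonic day 9.5 and from trophoblast stem cells (TSC) was hybridised to 40 Affymetrix expression arrays. Of these, 24 came from placentas: for each of 4 genes (Pparg, Rxra, Med1 and Ncoa6), 3 pools of 3 wild-type (WT) placentas and 3 pools of 3 null placentas, where, by the sample descriptions, pools with one number were litter-matched. The other 16 came from TSC that were differentiated for 2 or 4 days: 3 WT lines with and without 1 µM rosiglitazone (Rosi), an agonist of the nuclear receptor PPARg, and 2 Pparg-null lines with Rosi only.

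The deposited values are intensity: linear probe-set signals, which the authors scaled so that the mean of each array after trimming 2% of the probe sets at either end was 250 in the placentas and 500 in the TSC. The submitters' processing notes name RMA and MAS5 for the placentas and RMA and limma for the TSC, without saying what each was used for. The values are linear, reach 0 and are not quantile normalized, as MAS5 signals are. Arrays give no read depth, and their number limits the precision. The median signal of an array lay between 28.8 and 45.7 in the placentas and between 60.8 and 93.8 in the TSC.

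Of the 45101 probe sets, 64 controls were left out, as were 9160 without a gene symbol and 932 that name several genes. Symbols came from the array's annotation by way of RefSeq. Signals were analysed as log2 of the value plus 1, within each tissue only, because the tissues were scaled to different means. A gene was represented by its probe set with the highest mean, and genes whose mean did not exceed the 40th percentile of all probe sets (a signal of 16.9 in placentas and 35.7 in TSC) were left out. The files hold no detection calls, so this limit also served, by a choice made after the results were seen, as a floor for sizes of change. Where a group's mean was under it, the change was given as at least the mean of the brighter group over the mean of the dimmer one, with each array of the latter raised to the limit if lower. This left 12285 genes in placentas and 12393 in TSC.

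Linear models were fitted with limma 3.58.1 in R 4.3.3. The placenta model held all 24 arrays, a term for each of the 12 litter pairs and 1 null effect per cohort; it gave 8 residual degrees of freedom and 1.98 prior ones. The same comparisons without the replicate block gave 400, 232, 11 and 1757 genes for Pparg, Rxra, Med1 and Ncoa6. The pairing comes from the sample descriptions. Deviations of same-numbered pools from their group means correlated, across genes, which are not independent, at 0.139 to 0.298 for Ncoa6, 0.0237 to 0.0955 for Rxra, -0.00117 to 0.131 for Pparg and -0.0414 to 0.0314 for Med1, so the data show no shared deviation in every Pparg pair or in the Med1 pairs as a group. Differences between the null effects of Pparg and each other gene were tested as contrasts. The TSC model held 6 group means with no block and gave 10 residual and 2.16 prior degrees of freedom. Null and WT lines do not pair, but arrays of 1 line do within a genotype, so the line as replicate block was an alternative there. The residual degrees of freedom treat arrays of 1 line as independent, though these correlated at 0.483. Contrasts were Rosi against untreated WT cells and null against WT cells with Rosi at each day, null cells with Rosi against untreated WT cells, day 4 against day 2 in untreated WT cells, and the differences between days. Only the null lines' Rosi arrays exist, so genotype was compared at equal treatment first. A gene was called when its Benjamini-Hochberg adjusted p, over all genes of its tissue, was under 0.05. All p-values for genes are adjusted ones from limma unless named otherwise, and signals are means ± SD over pools or lines, while log2 changes carry the standard error of the fit. Pools and lines are separate samples by their labels. The p-values measure only the spread between these samples, and each null TSC group has 2 lines.

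Before the data were examined, 25 gene lists were fixed: labyrinth and syncytiotrophoblast, spongiotrophoblast and glycogen cells, trophoblast giant cells, trophoblast stem cells, epithelial keratins and junctions, lipid uptake and storage, fatty acid oxidation, fatty acid synthesis, cholesterol synthesis, glycolysis and lactate, nutrient transport, steroid synthesis, retinoid response, nuclear receptors and coregulators, hypoxia response, proliferation, endoplasmic reticulum stress, interferon response, 6 lists of other cell types (yolk sac endoderm, decidua, endothelium, mesenchyme, erythroid and immune cells) and sex-linked genes. The glycolysis and hypoxia lists share 5 genes; the other lists share none. Some members have no probe set of their own, among them Prl3d1, Prl2c2 and Prl3b1 of giant cells, Gcm1, Syna and Synb of the labyrinth, and Hmgcr and Ldlr of cholesterol synthesis. Lists were tested against all other genes with camera at a preset correlation of 0.01 and with an estimated correlation, adjusted over the 25 lists of a comparison. Of the 400 list tests, 63 passed with the preset correlation and 0 with an estimated correlation, and fry passed 58, with 35 of them shared with camera in the same direction. Members were also adjusted over the list alone.

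The named genes follow a rule fixed with the lists: the targeted gene and Muc1; the called genes with the highest and lowest changes that moved one way in every litter pair or whose TSC ranges did not overlap; up to 4 called members of each list; genes called in one direction in at least 3 null placentas; and each gene behind a count of 5 or fewer. Further rules, alternatives and splits of the samples were fixed at the same time. The alternatives were other filters, the mean of a gene's probe sets, quantile normalization, centring each array on its median, limma's trend and robust options, a 2-fold minimum, other blocks, fits of single comparisons and leaving out each replicate. Figures were drawn with Python 3.11.15 and matplotlib 3.10.9.

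The procedure was tested on simulated data with 200 changed genes. With the placenta design it recovered 46% of genes with a true log2 change of 0.5, 79% at 1 and 92% at 2, and 7.5% of 160 calls were false. With the Rosi design at day 4 it recovered 2%, 21% and 64%, and with the null TSC design at day 4 it recovered 0%, 17% and 64%. A list shifted by 0.5 was called and 0 of the other 24 were. The simulated genes varied independently of each other, so this does not test list calls where genes are correlated. No array pair held identical values, and no sample or probe set was left out as an outlier.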

Results

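Expression was measured on 24 arrays of placentas and 16 arrays of differentiating TSC. Each of the 4 placental cohorts held 3 WT and 3 null pools, and each pool held 3 placentas taken at embryonic day 9.5 after the decidua and yolk sac had been dissected away. The TSC series held 3 WT lines, untreated and with Rosi, and 2 Pparg-null lines with Rosi, each at days 2 and 4 of differentiation. TSC are trophoblast stem cells, which form giant and other placental cells in culture, and Rosi is rosiglitazone, a PPARg agonist. The median signal of an array lay between 28.8 and 45.7 in the placentas and between 60.8 and 93.8 in TSC, and the number of arrays limits the precision of all values. Replicates were alike: Pearson correlations within a group, taken across probe sets, which are not independent replicates, lay between 0.945 and 0.966 in the placentas and between 0.869 and 0.953 in TSC. Across tested genes, WT line 3 had the lowest mean correlation with the other lines in each of its 4 groups, between 0.910 and 0.941.

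The targeted transcript was read first in every sample. Pparg, the nuclear receptor under study, had signals of 2.5 to 8.9 in the 3 Pparg-null pools and 913 to 1225 in their WT pools. Ncoa6, a nuclear receptor coactivator, had 6 to 19.4 in null and 957 to 1183 in WT pools. Rxra, the heterodimer partner of PPARg, was lowered but not lost, at 252 to 279 in null and 502 to 620 in WT pools, and a second Rxra probe set had means of 115 and 156. Its remaining probe set was near the floor, at 10.2 and 3.63. Med1, a subunit of the Mediator complex, had 200 to 262 in null and 568 to 698 in WT pools. Of its 7 probe sets 5 were lower in null pools, and the other 2 had means of 262 in null and 170 in WT pools and of 44.3 and 43.2. In TSC, Pparg had 3.1 to 13.2 in the null cultures and 1145 to 3333 in the WT cultures.

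**Figure D1:**
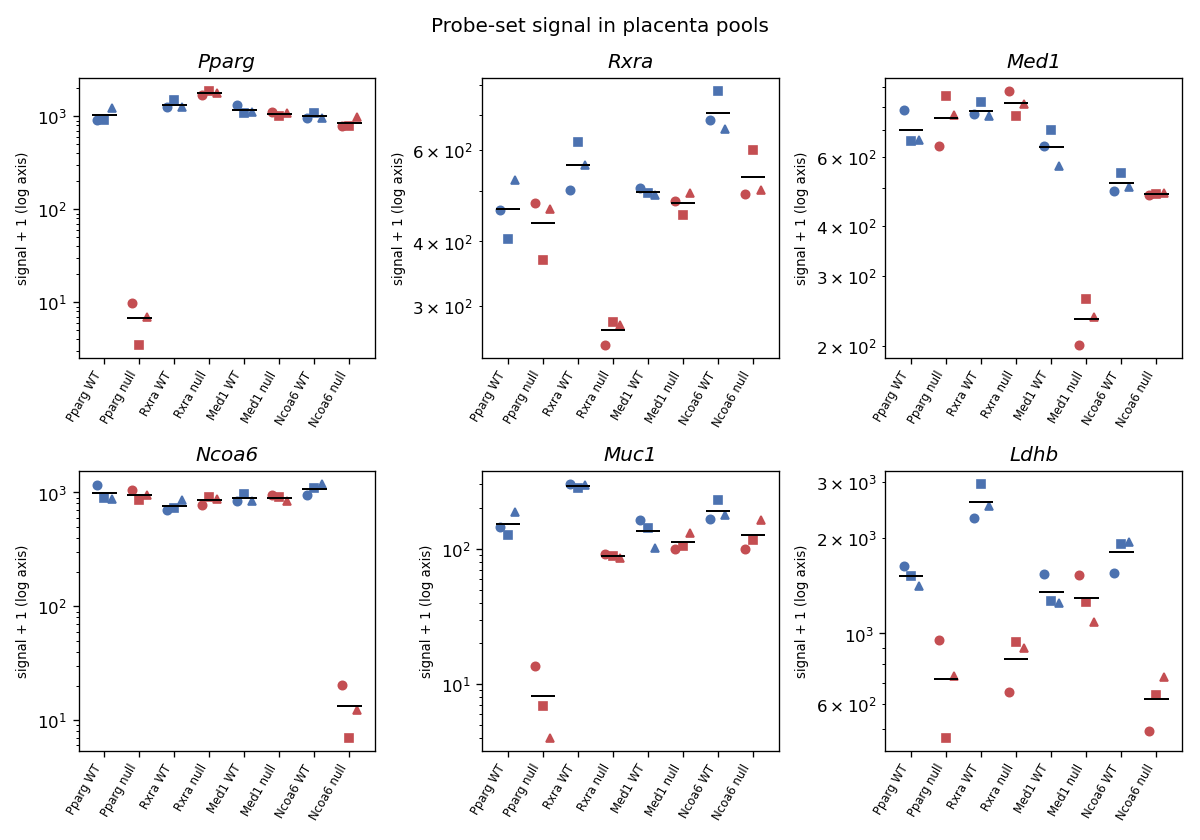
Signal plus 1 on a log axis for 6 genes in the 8 placental groups, with WT pools in blue, null pools in red, 1 point per pool and a bar at the group mean. Pparg and Ncoa6 are near the floor in their own null pools, and Rxra and Med1 are lowered in theirs. Mean Muc1 is 151 in Pparg WT and 7.2 in Pparg-null pools, and 292 in Rxra WT and 87.2 in Rxra-null pools.

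The comparison of Pparg-null with WT placentas asks which transcripts depend on PPARg in the placenta at midgestation. Muc1, a membrane mucin of the trophoblast, fell from 151 ± 30.8 to 7.2 ± 4.98 (SD, n = 3 pools; adjusted p = 0.000375). As 7.2 is under the filter limit of 16.9, its fall is given as a bound against that limit, at least 8.91-fold, and changes of other genes with a group under the limit are given in the same way. Gcgr, the glucagon receptor, fell at least 3.44-fold and Pex5l at least 2.30-fold. Ceacam11 changed by -3.35 ± 0.57 on the log2 scale. Rarres2, which encodes the adipokine chemerin, changed by -2.07 ± 0.25, the potassium channel Kcnj13 by -2.05 ± 0.21 and the prolactin family member Prl7b1 by -1.87 ± 0.37. Among the genes that rose were the Wnt regulator Dact2 (2.40 ± 0.32), the Myc family gene Mycl (at least 2.75-fold), the pluripotency-associated Dppa5a (2.03 ± 0.17; 204 ± 38.2 to 835 ± 162), the pattern receptor Nod1 (at least 3.74-fold), Dcxr (1.93 ± 0.29), Tfcp2l1 (1.81 ± 0.21), the chemokine receptor Cxcr4 (1.77 ± 0.20) and Lrrn4cl (1.68 ± 0.19). These 8 genes and the 7 named as lower passed the test, with adjusted p between 0.000375 and 0.0401. Prl7b1 was -1.20 without replicate 3 and -2.08 without replicate 4 and not called in either case. Ceacam11 was -4.13 without replicate 1, and -3.13 and -2.80 without replicates 3 and 4, where its call was lost. The calls of Mycl and Pex5l were also lost without replicate 3 or 4, and that of Nod1 without any 1 replicate.

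In all, 358 of 12285 genes were called, 146 higher and 212 lower, and 73 of them changed by at least 2-fold. Each of the 358 moved one way in all 3 litter pairs, and the fit without the replicate block called 400. At an unadjusted p under 0.05 there were 2188 genes where chance alone would give 614. The ratio of 3' to 5' signal of Gapdh, a measure of RNA quality, was 0.744 to 0.777 in null and 0.771 to 0.794 in WT pools, and lower in the null pool of each of the 3 pairs. Centring each array on its median moved the median change of all genes from 0.00 to -0.13 and the share of calls that were lower from 59.2% to 87.9%. The count rested on the number of arrays: it was 169 without replicate 3, 148 without replicate 4 and 0 when the 6 arrays were fitted alone. With no filter on low signals it was 170, and with limma's trend and robust options 573. Of the 40 named calls 22 were lost without 1 replicate or another. Among the genes given below, the calls of Acaa2, Aldoa, Fabp5, Folr1, Pfkl and Sc5d were lost without any 1 replicate. Those of Ankrd37, Hand1, Ndrg1 and Scd1 were lost without replicate 1 or 4, and those of Atf3 and Cldn4 without replicate 3 or 4. Bst2 lost its call without replicate 1 or 3, and Dgat1 without replicate 4.

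Lipid genes went both ways in the Pparg-null placentas. Of 23 tested members of lipid uptake and storage, 2 rose, 2 fell and 19 were not called (5 and 5 adjusted over the list alone). Lpin1, a phosphatidate phosphatase of triglyceride synthesis, rose by 0.89 ± 0.07 and the fatty acid binding protein Fabp5 by 0.38 ± 0.08. Dgat1, which completes triglycerides, changed by -0.66 ± 0.10 and Angptl4 by -0.74 ± 0.10; Angptl4 is an inhibitor of lipoprotein lipase, so its known action runs against the name of the list. Both stearoyl-CoA desaturases rose, Scd1 by 0.53 ± 0.09 and Scd2 by 0.52 ± 0.07, and they were the called genes among 10 of fatty acid synthesis, with the same 2 adjusted over the list alone. Of 15 fatty acid oxidation genes 1 rose, the thiolase Acaa2 (0.33 ± 0.07), with 2 higher and 2 lower adjusted over the list alone. Cholesterol synthesis was higher as a list (adjusted p = 0.000693; adjusted p = 0.367 with an estimated correlation), with 14 of 15 genes above 0 and a median of 0.19. The sterol desaturase Sc5d was its called gene (0.33 ± 0.07), and 2 rose adjusted over the list alone.

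The list of glycolysis and lactate was also higher (adjusted p = 0.00113; adjusted p = 0.443 with an estimated correlation), with 2 genes called higher, 1 lower and 11 not called, and with 5 higher and 1 lower adjusted over the list alone. Pfkl (0.43 ± 0.09) and Aldoa (0.29 ± 0.06) encode glycolytic enzymes. Ldhb, a lactate dehydrogenase subunit that favours pyruvate formation, changed the other way (-1.14 ± 0.15; 1518 ± 109 to 717 ± 241). Genes of the hypoxia response were higher (adjusted p = 2.36e-05; adjusted p = 0.367 with an estimated correlation): Ankrd37 (0.92 ± 0.17) and Ndrg1 (0.53 ± 0.11) were called of 15, and 7 adjusted over the list alone. Among trophoblast lists, 1 of 10 labyrinth genes fell, which was Gcgr (3 adjusted over the list alone), and 1 of 9 giant cell genes rose, the transcription factor Hand1 (0.45 ± 0.09; 1 adjusted over the list alone). Of 12 keratin and junction genes, Cldn4 rose (0.66 ± 0.14) and Muc1 fell, with 3 higher and 1 lower adjusted over the list alone. The folate receptor Folr1 was the called gene of 20 in nutrient transport (0.57 ± 0.13; 1 adjusted over the list alone).

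Bst2 (-0.55 ± 0.10) and Atf3 (-0.49 ± 0.10) were the called genes of the interferon and endoplasmic reticulum stress lists. Adjusted over the list alone there were 1 higher and 4 lower of 8 interferon genes and 1 lower of 11 stress genes. Of 12 nuclear receptors and coregulators only Pparg was called, on both counts. The other lists had 0 genes called by limma and list adjusted p between 0.16 and 0.647: spongiotrophoblast, stem cells, steroid synthesis, retinoid response, proliferation, yolk sac endoderm, decidua, endothelium, mesenchyme, erythroid and immune cells, and sex-linked genes. Adjusted over the list alone, 1 stem cell gene and 1 decidual gene were higher, and 3 erythroid and 1 mesenchymal gene were lower. The pools differed in sex-linked signal: the Y-linked Eif2s3y ranged from 237 to 953 in WT and from 0.3 to 685 in null pools (log2 change -3.13 ± 1.88, adjusted p = 0.43). With the mean Y-linked signal as a covariate, a setting added after the data were seen, 175 genes were called. The changes of the 357 called genes other than Pparg kept their sign and size (median ratio 0.983, quartiles 0.931 to 1.03), while their median standard error went from 0.111 to 0.120.

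The comparison of Rxra-null with WT placentas asks the same of the partner receptor. Among the genes that fell were Ghrh, which encodes growth hormone-releasing hormone (-2.93 ± 0.27), Ceacam11 (-2.84 ± 0.57), Ceacam13 (-2.44 ± 0.44), Insc (at least 5.82-fold) and Prelp (at least 1.65-fold). 4933407O12Rik was called lower with means of 12.6 and 3.3, both under the filter limit, so no size is given. Muc1 went from 292 ± 9.43 to 87.2 ± 3.4 (SD, n = 3 pools; -1.73 ± 0.34, adjusted p = 0.0383 from limma). Among the genes that rose were the secreted glycoprotein Stc1 (1.96 ± 0.34), the intermediate filament gene Prph (1.92 ± 0.30), Pi16 (at least 2.21-fold), Blnk (1.82 ± 0.22), Add2 (at least 1.14-fold) and the placental cathepsin Cts8 (1.70 ± 0.23). Rxra itself changed by -1.06 ± 0.07 (adjusted p = 0.000267). These 14 genes had adjusted p between 0.000267 and 0.0414. The calls of Ceacam11, Ceacam13, Muc1, Stc1 and Prph were lost without any 1 replicate. Those of 4933407O12Rik, Add2 and Cts8 were lost without replicate 3 or 4.

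Altogether 198 genes were called, 88 higher and 110 lower, 52 of them by at least 2-fold, against 1645 at an unadjusted p under 0.05. Without the replicate block 232 were called. Centring each array on its median gave 131 genes and 68.7% lower calls in place of 55.6%. Leaving out replicates 2, 3 and 4 in turn gave 52, 59 and 58 genes, and the 6 arrays alone gave 0. Sex-linked signal stood apart from the other cohorts: Eif2s3y was 2.8 to 5.8 in the 3 WT pools and 247 to 545 in the 3 null pools. The sex-linked list was higher (adjusted p = 0.0491; adjusted p = 0.669 with an estimated correlation; 0 of 4 genes called and 3 adjusted over the list alone), and with the Y-linked signal as a covariate 101 genes were called. The changes of the 197 called genes other than Rxra kept their sign and size (median ratio 1.01, quartiles 0.939 to 1.07), while their median standard error went from 0.112 to 0.127.

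Lipid genes in the Rxra-null placentas included Angptl4 (165 ± 15.6 to 82.3 ± 12), which was lower, Dgat1 (-0.57 ± 0.10) and Lpin1 (0.57 ± 0.07), so 1 of 23 uptake and storage genes rose and 2 fell (1 and 3 adjusted over the list alone). Scd1 (0.51 ± 0.09) and Scd2 (0.33 ± 0.07) rose of 10 synthesis genes, with 3 higher and 1 lower adjusted over the list alone. Decr1, an enzyme of unsaturated fatty acid oxidation, fell by 0.83 ± 0.10, the 1 gene called of 15 and also 1 adjusted over the list alone. The hypoxia response was higher as a list (adjusted p = 1.44e-05; adjusted p = 0.669 with an estimated correlation), with 14 of 15 genes above 0, 0 called over all genes and 6 adjusted over the list alone. Glycolysis and lactate was higher (adjusted p = 0.0197; adjusted p = 0.751 with an estimated correlation), and lost the call without the replicate block (adjusted p = 0.0871). Its called gene, Ldhb, fell by 1.65 ± 0.15, and adjusted over the list alone 2 rose and 1 fell. The folate carrier Slc19a1 (0.41 ± 0.08) and the endothelial Pecam1 (0.50 ± 0.10) were the called genes of 20 and 14 in their lists (2 and 1 adjusted over the list alone). The calls of Dgat1, Scd1, Scd2, Slc19a1 and Pecam1 were lost without any 1 replicate.

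For Med1-null placentas the question was whether loss of this coactivator subunit changes the same transcripts. The called genes numbered 4, all lower: Med1 (-1.45 ± 0.13, adjusted p = 0.00275), the chromatin remodelling subunit Smarce1 (-1.11 ± 0.08, adjusted p = 0.00061), the RNA-binding Taf15 (-1.02 ± 0.11, adjusted p = 0.00957) and the methyltransferase Mettl16 (-0.90 ± 0.10, adjusted p = 0.00957). All 4 lie on chromosome 11. Smarce1 has another probe set above the filter, which had 570 ± 5.61 in WT and 584 ± 28.1 in null pools, so its call held for 1 probe set only. Another probe set of Taf15 above the filter changed by -0.16. Muc1 had 135 ± 31.4 in WT and 111 ± 16.5 in null pools (-0.27 ± 0.34, adjusted p = 0.811).

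At an unadjusted p under 0.05 there were 1491 genes in the Med1 comparison. The count was 12 without replicate 2, 11 without the replicate block, 22 with limma's trend and robust options, 13 with a pseudocount of 32 and 0 with the 6 arrays alone. Median centring moved the median change of all genes to -0.11. The decidual list was higher (adjusted p = 0.0279; adjusted p = 0.539 with an estimated correlation): 0 of 9 markers were called, and 3 were higher and 1 lower adjusted over the list alone, with Pgr, the progesterone receptor, at 0.98 ± 0.28 (adjusted p = 0.253). The hypoxia list was higher (adjusted p = 0.0468; adjusted p = 0.61 with an estimated correlation), with 0 of 15 genes called on both counts and Adm at 0.84 ± 0.35.

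Loss of Ncoa6 had the widest effect, and its comparison asks which placental transcripts need this coactivator. Markers of the spongiotrophoblast fell: Tpbpb changed by -4.53 ± 0.56 (434 ± 96.7 to 17.6 ± 2.92), Flt1 by -1.53 ± 0.26, Tpbpa by -1.38 ± 0.18 (10239 ± 802 to 3955 ± 491) and the transcription factor Ascl2 by -0.74 ± 0.09. The giant cell genes Prl5a1 (1.36 ± 0.27), Bhlhe40 (0.89 ± 0.09) and Hand1 (0.86 ± 0.09; 3207 ± 302 to 5810 ± 357) rose. The hypoxia genes Vegfa (2.23 ± 0.19), Adm (1.88 ± 0.35), Egln3 (0.82 ± 0.19) and Pdk1 (0.45 ± 0.13) rose as well. Adm was 1.28 without replicate 1 and stayed called, while the calls of Egln3 and Pdk1 were lost without any 1 replicate. Outside these groups genes with a null mean under the filter limit fell, namely Insc (at least 7.32-fold), C1qtnf1 (at least 6.67-fold), Unc5a (at least 4.60-fold), Slit1 (at least 2.58-fold), Cnmd (at least 1.93-fold) and Cdhr4 (at least 1.73-fold). Gad1 (2.41 ± 0.35), Nppb (2.33 ± 0.22), H2-Ab1 (2.11 ± 0.56), Tns4 (2.09 ± 0.16), Bfsp1 (2.03 ± 0.29), Clec1a (2.01 ± 0.24) and Nacc1 (2.00 ± 0.33) rose. The call of H2-Ab1 was lost without any 1 replicate, and those of Slit1 and Prl5a1 without replicate 1 or 2.

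In Ncoa6-null placentas 1818 genes were called, 678 higher and 1140 lower, 320 of them by at least 2-fold, against 3511 at an unadjusted p under 0.05. Without the replicate block there were 1757. Centring each array on its median gave 52.3% lower calls in place of 62.7%. Leaving out replicates 1, 2 and 4 gave 1009, 777 and 869 genes, the 6 arrays alone 592 and no filter 1183. Of the 84 named calls 28 were lost without 1 replicate or another. Among the genes given below, the calls of Dlx3, Fasn, Hk1, Nrip1, Ocln, Pecam1 and Tgm2 were lost without any 1 replicate. Those of Epcam, Kdr and Tie1 were lost without replicate 1 or 2, and those of Cpt1a and Ifit2 without replicate 1 or 4. Des, Hand2 and Nr1h3 lost their calls without replicate 2 or 4. Muc1 had 190 ± 33.3 in WT and 125 ± 33.5 in null pools (-0.62 ± 0.34, adjusted p = 0.269). The ratio of 3' to 5' signal of Gapdh was 0.834 to 0.890 in null and 0.803 to 0.839 in WT pools.

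The spongiotrophoblast list was lower (adjusted p = 0.00461; adjusted p = 0.248 with an estimated correlation), with 4 of 10 genes lower, 0 higher and 6 not called, and 7 lower adjusted over the list alone. Of 9 giant cell genes 3 rose (3 higher and 1 lower adjusted over the list alone; list adjusted p = 0.15). The stem cell factors Eomes (-1.38 ± 0.23), Esrrb (-1.02 ± 0.13) and Cdx2 (-0.82 ± 0.12) were the 3 genes lower of 10, on both counts (list adjusted p = 0.071). The labyrinth genes Ovol2 (-0.77 ± 0.12) and Dlx3 (-0.36 ± 0.11) were the 2 called of 10, on both counts. Proliferation was lower (adjusted p = 0.00461; adjusted p = 0.268 with an estimated correlation), with 8 of 17 lower on both counts, among them Birc5 (-0.56 ± 0.09) and Plk1 (-0.50 ± 0.07). Of 15 hypoxia genes 4 rose, on both counts, and the list did not pass (adjusted p = 0.072). Nuclear receptors and coregulators were lower (adjusted p = 0.0234; adjusted p = 0.175 with an estimated correlation): Ncoa6, Nr1h3 (at least 1.33-fold), Rxra (-0.41 ± 0.07) and Nrip1 (-0.30 ± 0.08) of 12, and 6 lower and 1 higher adjusted over the list alone. Ncoa6 is the targeted gene, so its fall was fixed in advance and enters both the list test and these counts. The list was not tested without it.

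Lipid uptake and storage was lower in Ncoa6-null placentas (adjusted p = 0.0301; adjusted p = 0.22 with an estimated correlation), with 7 of 23 genes lower and 4 higher (8 and 4 adjusted over the list alone). Lipoprotein lipase, Lpl, changed by -1.42 ± 0.12, its inhibitor Angptl4 by -1.71 ± 0.10 and Dgat2 by -0.98 ± 0.08, while the monoglyceride lipase Mgll, which breaks lipid down, rose by 1.12 ± 0.09. Of 15 oxidation genes 5 fell on both counts, among them Slc25a20 (-1.33 ± 0.12), Decr1 (-0.90 ± 0.10) and Cpt1a (-0.59 ± 0.11; list adjusted p = 0.072). Of 10 synthesis genes 4 fell on both counts, among them Fads2 (-0.89 ± 0.12) and Fasn (-0.37 ± 0.09; list adjusted p = 0.0534). Without the replicate block the lists of oxidation and synthesis passed (adjusted p = 0.0381 and 0.0402). Nutrient transport was lower (adjusted p = 0.0044; adjusted p = 0.175 with an estimated correlation), with 6 of 20 genes lower and 8 adjusted over the list alone, among them Slc7a8 (-1.54 ± 0.23) and Abca1 (-0.99 ± 0.14). Of 14 glycolysis genes Ldhb (-1.55 ± 0.15) and Hk1 (-0.48 ± 0.10) fell and Pdk1 rose, on both counts. Crabp2 fell (-1.75 ± 0.16) and Tgm2 rose (0.30 ± 0.09) of 8 retinoid genes, on both counts.

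Markers of other cell types moved with these groups in the Ncoa6-null pools. The decidual list was lower (adjusted p = 0.000137; adjusted p = 0.175 with an estimated correlation): 4 of 9 fell, Prl8a2 (-1.66 ± 0.18), Des (-1.19 ± 0.24), Cryab (-1.16 ± 0.19) and Hand2 (-0.96 ± 0.18), and 8 adjusted over the list alone. Mesenchyme was lower (adjusted p = 0.00298; adjusted p = 0.214 with an estimated correlation), with 6 of 13 lower, such as Pdgfrb (-0.80 ± 0.14), and 8 adjusted over the list alone. The endothelial list was lower (adjusted p = 0.0194; adjusted p = 0.295 with an estimated correlation), where Emcn (-0.89 ± 0.13), Tie1 (-0.78 ± 0.16) and Kdr (-0.61 ± 0.15) fell and Pecam1 rose (0.39 ± 0.10) of 14, with 6 lower and 1 higher adjusted over the list alone. Of 8 interferon genes 3 fell, among them Ifit2 (at least 1.61-fold; 3 lower and 1 higher adjusted over the list alone). Of 12 keratin and junction genes Ocln (at least 1.46-fold) and Epcam (-0.50 ± 0.10) fell (3 adjusted over the list alone), and of 15 cholesterol synthesis genes Srebf2 (-0.50 ± 0.07), on both counts.

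To ask how far the mutants share their changes, calls were intersected. Pparg-null and Rxra-null placentas shared 50 lower genes where 1.90 would be shared by chance (Fisher's exact test over 12285 genes, p = 4.13e-60) and 35 higher genes (1.05 by chance, p = 1.37e-45), and 0 genes were called in opposite directions, where 1.52 and 1.31 would be by chance. By the same exact test, Pparg-null and Ncoa6-null placentas shared 88 lower (19.7 by chance, p = 1.54e-36) and 25 higher genes (8.06 by chance, p = 3.75e-07), with 7 and 14 genes in opposite directions. Rxra-null and Ncoa6-null placentas shared 73 lower and 33 higher genes (10.2 and 4.86 by chance). Genes are not independent, so these p-values are descriptive. As a set, the genes lower in Pparg-null placentas were lower in Rxra-null placentas, which share no array with them (187 of 211 below 0, median -0.26; adjusted p = 0.0012 with an estimated correlation), and in Ncoa6-null placentas (171 of 211, median -0.28; adjusted p = 0.0227 with an estimated correlation). In the fit without the replicate block, which gave 400 calls in Pparg-null placentas, these 2 sets had adjusted p = 0.00939 and 0.0846 with an estimated correlation, so the second did not pass. In Med1-null placentas 124 of 211 were below 0 (median -0.04; adjusted p = 0.391 with an estimated correlation).

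Called in one direction in at least 3 of the 4 null placentas were 54 genes, and 0 were called by limma in all 4. The shared genes with the highest mean changes were Ceacam11, Rarres2, Ghrh, Ldhb, Hrct1, Eva1a, 4931406C07Rik and Car5b, which fell, and Dppa5a and Elovl7, a fatty acid elongase, which rose. In Rxra-null placentas the calls of Ceacam11, Rarres2, Eva1a and Car5b were lost without any 1 replicate. So were those of Elovl7 in Pparg-null and Ceacam11 in Ncoa6-null placentas. In Pparg-null placentas Ghrh lost its call without replicate 3 or 4 and Hrct1 without replicate 1 or 3. In Rxra-null placentas Hrct1 lost its call without replicate 3 or 4 and Elovl7 without replicate 2 or 3. In Ncoa6-null placentas Ghrh lost its call without replicate 4 and Dppa5a without replicate 2 or 4. Ghrh, for example, changed by -1.50 ± 0.27, -2.93 ± 0.27 and -1.40 ± 0.27 in Pparg-null, Rxra-null and Ncoa6-null placentas and by 0.16 ± 0.27 in Med1-null placentas. Eva1a changed by -1.67 ± 0.14, -0.95 ± 0.14 and -1.32 ± 0.14, against 0.12 ± 0.14 with Med1. Across genes, which are not independent replicates, the changes of Pparg-null placentas correlated with those of Rxra-null (r = 0.317), Ncoa6-null (r = 0.237) and Med1-null placentas (r = 0.0450).

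**Figure D2:**
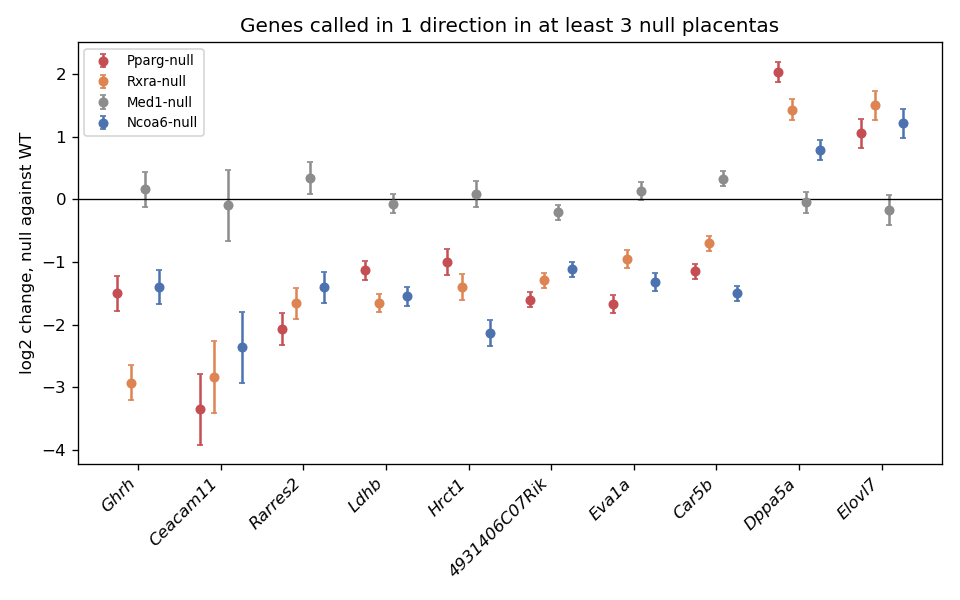
Log2 change against WT (points) with its standard error (bars) in the 4 null placentas for 10 of the 54 genes called in one direction in at least 3 of them. The 10 shown have the largest mean changes. Ghrh lies between -2.93 and -1.40 in Pparg-null, Rxra-null and Ncoa6-null placentas and at 0.16 in Med1-null placentas.

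Tests of the difference itself compared the null effects of the mutants. Each mutant has its own cohort of pools, so a difference between mutants cannot be told apart from one between cohorts. The cohorts differ, for example, in the ratio of 3' to 5' signal of Gapdh. It was 0.771 to 0.794 in Pparg WT and 0.876 to 0.889 in Rxra WT pools. Between Pparg-null and Rxra-null placentas 3 genes differed (1048 at an unadjusted p under 0.05): Pparg itself (adjusted p = 2.52e-06), Rxra (0.96 ± 0.09) and Dcaf12l1 (-1.67 ± 0.19, adjusted p = 0.0263), which fell from 899 ± 147 to 264 ± 89.9 in Pparg-null pools and had 1046 ± 45.9 and 954 ± 94.6 in the Rxra cohort. The difference in Muc1 was not called (adjusted p = 0.16). Between Pparg-null and Med1-null placentas 101 genes differed, 46 with the higher change in Pparg-null and 55 with the lower, among them Muc1 (adjusted p = 0.0101), Rarres2 (-2.41 ± 0.35), Eva1a (-1.80 ± 0.20) and Dppa5a (2.08 ± 0.24). Between Pparg-null and Ncoa6-null placentas 598 differed, 379 higher and 219 lower, among them Muc1 (adjusted p = 0.00389). For Pparg and Muc1 no size is given, since their Pparg-null signals are under the filter limit. Without the replicate block the counts were 10, 106 and 552. Labyrinth genes differed as a list between Pparg-null and Rxra-null placentas (adjusted p = 0.00262; adjusted p = 0.092 with an estimated correlation), with all 10 lower in the Pparg-null change, 0 called by limma and 2 adjusted over the list alone. Interferon (0.0123), sex-linked (0.0187) and endothelial genes (0.0367) were lower and proliferation (0.0187) higher as lists, with adjusted p = 0.338, 0.338, 0.504 and 0.504 with an estimated correlation. In these 4 lists 0 genes were called, and 3, 3, 0 and 0 adjusted over the list alone; interferon had 0.0940 without the replicate block. Between Pparg-null and Med1-null placentas glycolysis and lactate was higher (adjusted p = 0.0440; adjusted p = 0.679 with an estimated correlation; 0 of 14 called, 3 higher and 1 lower adjusted over the list alone), with 0.153 without the replicate block.

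Of the 25 lists 11 differed between Pparg-null and Ncoa6-null placentas, each higher in the Pparg-null change. Decidua had an adjusted p of 3.6e-05 (adjusted p = 0.171 with an estimated correlation; 2 of 9 genes called, 8 adjusted over the list alone) and trophoblast stem cells one of 0.00463 (adjusted p = 0.171 with an estimated correlation; 3 of 10 and 4 adjusted over the list alone). Fatty acid synthesis had 0.000535 (adjusted p = 0.171 with an estimated correlation; 4 of 10 and 5 adjusted over the list alone). Proliferation (0.000443; 4 of 17 called, 9 adjusted over the list alone), cholesterol synthesis (0.00297; 1 of 15, 3) and glycolysis (0.00408; 2 of 14, 3) had adjusted p = 0.175, 0.226 and 0.263 with an estimated correlation. Lipid uptake (0.00781; 7 higher and 1 lower of 23, 9 and 2), nutrient transport (0.00828; 3 of 20, 5) and retinoid response (0.0437; 1 of 8, 2 higher and 1 lower) had adjusted p = 0.171, 0.171 and 0.174 with an estimated correlation. Spongiotrophoblast (0.0234; 2 of 10, 5) and mesenchyme (0.0354; 1 of 13, 1) both had adjusted p = 0.263 with an estimated correlation, and mesenchyme 0.151 without the replicate block. After median centring the median difference of all genes was -0.17, a shift as large as the median of the glycolysis list (0.17), and 74.5% of the calls were lower in place of 36.6%. The 598 became 279 and 384 without Pparg replicates 1 and 3, and 329, 193 and 228 without Ncoa6 replicates 1, 2 and 4. The 101 became 59 and 44 without Pparg replicates 1 and 4, and 19, 57 and 29 without Med1 replicates 1, 2 and 3. The 3 genes became 5 without Pparg replicate 1 and 1 without Rxra replicate 4.

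The TSC comparisons ask what the agonist does in WT cells and what depends on the receptor. With Rosi, 0 of 12393 genes were called by limma at day 2 (160 at an unadjusted p under 0.05, 620 by chance) and 1 at day 4 (473 at an unadjusted p under 0.05). The gene called was Hrh3, a histamine receptor gene, which fell from 64.5 ± 19.1 to 9.43 ± 2.21 at day 4 (SD, n = 3 lines; at least 1.80-fold against the TSC filter limit of 35.7, adjusted p = 0.0113 from limma) and had 36.2 ± 4.47 and 57.7 ± 3.01 at day 2. Muc1 had 238 ± 98.4 without and 457 ± 212 with Rosi at day 2 and 324 ± 80.6 and 808 ± 241 at day 4 (1.30 ± 0.57, adjusted p = 1). Ctsq, a giant cell cathepsin, had 932 ± 499 and 6546 ± 2838 at day 4 (2.88 ± 0.69, adjusted p = 0.91). Pparg changed by -0.61 ± 0.35 and -0.55 ± 0.35 at the 2 days, and neither was called. The counts at day 2 and day 4 above come from the fit without a block; with the line as replicate block, 598 and 1280 genes had an unadjusted p under 0.05 at days 2 and 4, and 0 were called at either.

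The WT lines pair by number, with same-line correlations of 0.510 to 0.734 at day 2 and 0.278 to 0.424 at day 4 across genes, which are not independent replicates. Adding limma's trend and robust options to the replicate block, after the data were seen, gave 0 and 19 genes. The Hrh3 call was also lost without untreated replicate 2 or Rosi replicates 1 or 2 at day 4 (0 genes each), and was 1 of 2 calls without untreated or Rosi replicate 3. The cholesterol synthesis list was lower with Rosi at day 4 (adjusted p = 0.0376; adjusted p = 0.639 with an estimated correlation; 13 of 15 below 0) and at day 2 (adjusted p = 0.0428; adjusted p = 0.735 with an estimated correlation). At day 2 the lists of spongiotrophoblast (adjusted p = 0.0428), nutrient transport (0.0428) and nuclear receptors (0.0499) were lower too (adjusted p = 0.735 with an estimated correlation for each). At day 4 both tested erythroid genes were lower (adjusted p = 0.0376; adjusted p = 0.344 with an estimated correlation). With the line as replicate block, cholesterol synthesis at day 2, nutrient transport and nuclear receptors had adjusted p = 0.0633 and the erythroid list 0.0985. In all of these lists 0 genes were called over all genes, and 1 erythroid gene and 0 others adjusted over the list alone.

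**Figure D3:**
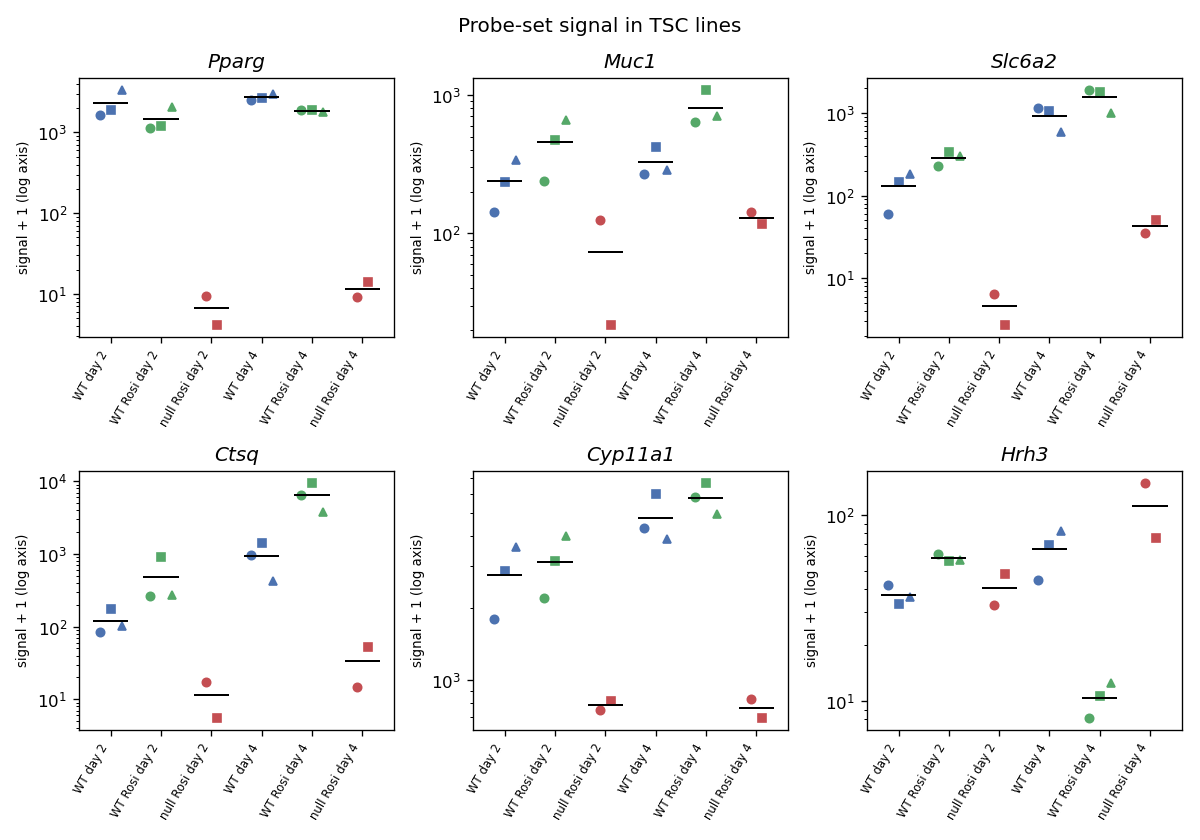
Signal plus 1 on a log axis for 6 genes in the 6 TSC groups, with untreated WT lines in blue, Rosi-treated WT lines in green and Rosi-treated null lines in red, 1 point per line and a bar at the group mean. Pparg is at 13.2 or lower in every null culture, and mean Ctsq is 932 without and 6546 with Rosi in WT cells at day 4 and 32.9 in null cells.

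The comparison of Pparg-null with WT lines, both with Rosi, asks which transcripts need the receptor when the agonist is present. At day 4 Pparg fell at least 51.9-fold. Prl2b1, a prolactin family member, fell at least 62.8-fold (2243 ± 1462 to 5.7 ± 4.1; SD, 3 WT and 2 null lines), Ctsq at least 149-fold, Tpbpa at least 7.84-fold and Tnnt2 at least 5.53-fold, all with null means under the filter limit. The noradrenaline transporter Slc6a2 changed by -5.15 ± 0.51 and the cathepsin Ctsj by -4.93 ± 0.43 (19999 ± 2363 to 653 ± 23.6). Cyp11a1, which starts steroid synthesis, went from 5796 ± 862 to 762 ± 99.3 (-2.92 ± 0.32), and Muc1 from 808 ± 241 to 129 ± 19.6 (-2.61 ± 0.64, adjusted p = 0.042). Among the genes that rose were the nuclear receptor gene Nr4a3 (4.81 ± 1.02), Trim34a (3.95 ± 0.44), Rpgrip1 (3.79 ± 0.49) and Tmprss2 (3.50 ± 0.88). Nr4a3 was 4.06 without WT Rosi replicate 2 and 6.03 without WT Rosi replicate 1, and Rpgrip1 4.47 and 3.10 without null replicates 1 and 2. The calls of Muc1 and Tmprss2 were lost without any 1 of the 5 arrays (Muc1 -2.76 to -2.38, Tmprss2 2.99 to 4.00), and that of Nr4a3 without any but WT Rosi replicate 1. With WT means under the limit, Trim30d rose at least 18.8-fold, 1700094J05Rik at least 9.72-fold, Myo7a at least 8.85-fold and Afm at least 4.60-fold. The call of Myo7a was lost without any 1 WT Rosi replicate, and that of 1700094J05Rik without WT Rosi replicate 3.

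At day 4, 475 genes were called, 128 higher and 347 lower, 410 of them by at least 2-fold, against 2331 at an unadjusted p under 0.05. Median centring moved the median change of all genes to -0.14 and gave 88.6% lower calls in place of 73.1%. The count was 255 without WT Rosi replicate 2, 290 without WT Rosi replicate 3 and 9 with the 5 arrays alone. Null line 1 had Xist at 387 and Eif2s3y at 2441 where null line 2 had Xist at 13778 and Eif2s3y at 2.5, and in every WT culture Xist was at least 9764. The lines therefore differ in sex-linked expression within the null genotype.

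Giant cell genes were lower as a list at day 4 (adjusted p = 1.78e-05; adjusted p = 0.16 with an estimated correlation): Ctsq, Ctsj, Prl2a1 (-2.24 ± 0.55) and Hand1 (-1.13 ± 0.28) fell of 8 genes, and 5 adjusted over the list alone. The call of Hand1 was lost without any 1 WT Rosi replicate, and that of Prl2a1 without WT Rosi replicate 2 or 3. Steroid synthesis was lower (adjusted p = 1.78e-05; adjusted p = 0.16 with an estimated correlation), with 4 of 5 genes called and 5 adjusted over the list alone: Cyp11a1, Cyp17a1 (-3.94 ± 0.93), Hsd17b2 (-3.88 ± 0.92) and Fdx1 (-1.76 ± 0.44). Cyp17a1 was -5.32 and Hsd17b2 -5.21 without null replicate 1, and -2.56 and -2.55 without null replicate 2. Both calls were lost without null replicate 2 or any 1 WT Rosi replicate, and that of Fdx1 without any 1 of the 5 arrays (-2.13 to -1.39). The remaining lists did not pass. In lipid uptake and storage Mgll (-4.50 ± 1.10) and Dgat1 (-1.09 ± 0.23) fell of 21, and in glycolysis Ldhb (-2.68 ± 0.51) and Aldoc (-1.09 ± 0.25) fell of 14. The desaturase Scd2 (1.24 ± 0.26) rose of 11 synthesis genes and the squalene epoxidase Sqle (1.45 ± 0.24) of 15 cholesterol genes. These 4 lists had as many called adjusted over the list alone. Mgll was -7.14 without null replicate 1 and -1.86 without null replicate 2, so its size differs between the null lines, and its call was lost without null replicate 2 or any 1 WT Rosi replicate. Ldhb was -3.30 and -2.06 without null replicates 1 and 2, and not called without the latter. Ppard fell (-1.67 ± 0.34) and Ppargc1b rose (1.22 ± 0.26) among 12 nuclear receptors and coregulators, whose count adjusted over the list alone was 2 higher and 2 lower beside 1 and 2. The calls of Aldoc, Scd2, Ppard and Ppargc1b were lost without WT Rosi replicate 2 or 3, and that of Dgat1 without WT Rosi replicate 3.

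Tpbpa fell and Pcdh12 (1.65 ± 0.39) rose of 7 spongiotrophoblast genes, and Muc1 fell and Cdh1 (0.71 ± 0.16) rose of 12 keratin and junction genes, on both counts. The call of Pcdh12 was lost without any 1 WT Rosi replicate, and that of Cdh1 without WT Rosi replicate 2 or 3. The median of the spongiotrophoblast list at day 4 was 0.72 while its mean was -0.26. Genes listed as markers of other cell types also fell, on both counts: the endothelial Cdh5 (-3.61 ± 0.54) and Esam (-2.98 ± 0.68) of 7, the decidual Des (at least 2.29-fold) and Wnt4 (at least 3.35-fold) of 4 and the mesenchymal Pdgfra (-2.23 ± 0.32) of 8. Esam was -3.85 without null replicate 1 and -2.12 without null replicate 2, and its call was lost without null replicate 2 or any 1 WT Rosi replicate. Des and Wnt4 lost their calls without WT Rosi replicate 1 or 2. WT cultures with Rosi had Cdh5 at 2559 ± 833, Esam at 4658 ± 1472 and Pdgfra at 1662 ± 347, and which cells of a culture carry these signals was not measured.

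At day 2, 22 genes were called between null and WT lines with Rosi, 5 higher and 17 lower, against 953 at an unadjusted p under 0.05. Pparg fell at least 41.2-fold, Ctsq at least 13.6-fold, Slc6a2 at least 8.04-fold, Ncmap at least 4.27-fold and Ccn5 at least 1.66-fold, all with null means under the filter limit. Ctsj (-4.60 ± 0.43), Hmgn5 (-2.46 ± 0.29) and Arhgap18 (-2.44 ± 0.42) fell as well. Trim34a (4.35 ± 0.44), Rpgrip1 (3.98 ± 0.49), Taf7l (2.58 ± 0.24), Trim30a (2.30 ± 0.36) and C3ar1 (1.26 ± 0.20) rose. Rpgrip1 was 4.76 without null replicate 1, and 3.20 and not called without null replicate 2, where Hmgn5 was -2.03. The call of C3ar1 was lost without any 1 WT Rosi replicate. Those of Ncmap, Ccn5, Arhgap18 and Cyp11a1 were lost without WT Rosi replicate 2 or 3. Trim30a lost its call without WT Rosi replicate 1 or 3, and Ctsq without WT Rosi replicate 2. Of the 17 lower genes 13 were also lower at day 4, and all 5 higher ones were higher, but both days use the same lines, so differences between lines recur and no chance value applies. Giant cell genes (adjusted p = 2.75e-07; 2 of 8 lower, 3 adjusted over the list alone) and steroid synthesis (adjusted p = 6.58e-08; 1 of 5 lower, which was Cyp11a1 at -1.95 ± 0.32, and 5 adjusted over the list alone) were lower. Both had adjusted p = 0.0619 with an estimated correlation. Fatty acid oxidation was higher (adjusted p = 0.00927; adjusted p = 0.192 with an estimated correlation; 14 of 15 above 0 and 0 called on both counts). Median centring moved the median change to 0.13 and gave 62.5% lower calls in place of 77.3%. The count was 11 and 9 without WT Rosi replicates 2 and 3, 10 without null replicate 2, 13 with no filter and 40 with a stricter one.

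Set against untreated WT lines, which differ in both genotype and treatment, the null lines with Rosi had 9 genes called at day 2 (2 higher and 7 lower; 645 at an unadjusted p under 0.05) and 184 at day 4 (32 higher and 152 lower; 1807). Slc6a2 (at least 3.60-fold), Ncmap (at least 2.85-fold) and Ctsj (-4.28 ± 0.43) were lower and Trim34a (4.43 ± 0.44) and Rpgrip1 (4.00 ± 0.49) higher at day 2. At day 4 Prl2b1 (at least 51.9-fold) and Ctsq (at least 21.2-fold) were lower and Trim30d (4.66 ± 0.99) and Myo7a (at least 8.27-fold) higher. The call of Ncmap was lost without untreated replicate 2 or 3. Prl2b1 lost its call without untreated replicate 1 or 2, and Myo7a without untreated replicate 1 or 3. Trim30d was 3.74 and 5.74 without untreated replicates 2 and 3 and was called without the latter only, and Rpgrip1 at day 2 was 4.78 without null replicate 1, and 3.22 without null replicate 2; it was not called without the latter or untreated replicate 2. Giant cell and steroid genes were lower at day 2 (adjusted p = 4.34e-09 and 2.01e-08; adjusted p = 0.0508 with an estimated correlation for both) and at day 4 (3.55e-06 and 7.74e-06; adjusted p = 0.15 with an estimated correlation for both). Giant cell genes called were 1 and 2 of 8 at days 2 and 4 (4 and 5 adjusted over the list alone), and steroid genes 0 and 1 of 5 (3 and 5 adjusted over the list alone). Fatty acid oxidation was higher at day 2 (0.00597; adjusted p = 0.161 with an estimated correlation). Of the 25 lists 5 passed at day 2 with the preset correlation, these lists among them, and 0 with an estimated correlation. Glycolysis (0.0121) and the endothelial (0.0298) and mesenchymal lists (0.0127) were lower at day 4, with adjusted p = 0.605, 0.316 and 0.316 with an estimated correlation. They had 1 gene called each, and 2, 4 and 1 adjusted over the list alone. Median centring moved the median change at day 4 to -0.19 and gave 93.6% lower calls in place of 82.6%. At day 4 the count was 79 and 90 without untreated replicates 1 and 2 and 387 without null replicate 1; at day 2 it was 4 without untreated replicate 2 and 17 without null replicate 1.

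With Rosi-treated WT lines as the reference of the TSC, placentas and TSC without Pparg shared 39 lower genes at day 4 (5.91 by chance among 11479 genes tested in both, Fisher's exact p = 1.90e-21), among them the targeted Pparg itself, Muc1, Ldhb, Dgat1 and Hrct1, and 10 higher genes (1.37 by chance, p = 1.1e-06), among them Tfcp2l1 and Scd2. In opposite directions 2 genes were shared, Hand1 and 1190005I06Rik, both higher in placentas and lower in TSC. At day 2 they shared 3 lower genes, Pparg, Morc4 and Arhgap18. With untreated WT lines as the reference, 6 lower genes were shared at day 4, Pparg among them (2.49 by chance, Fisher's exact p = 0.0391). There 3 higher genes were shared (0.332 by chance, Fisher's exact p = 0.00429), and 1 gene in opposite directions. Pparg is the targeted gene in both tissues, so its fall was fixed in advance and enters each of the overlaps of lower genes. These overlaps were not tested without it, so the Fisher's exact p of 0.0391 does not by itself show sharing beyond the target. The 2 genes outside the rule for named genes, 1190005I06Rik and Morc4, were named after their values were seen. Genes lower in Pparg-null placentas, induced by Rosi and lower in null TSC numbered 0, since 0 genes were called as Rosi-induced.

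Between days 4 and 2 in untreated WT lines 0 genes were called by limma without a block, with 1006 at an unadjusted p under 0.05. With the line as replicate block 156 were called, 98 higher and 58 lower, and 82 with the line as a random block. Ctsq (2.87 ± 0.69) and Tpbpa (3.54 ± 0.72) had the highest values of their lists, neither called. Proliferation was lower at day 4 (adjusted p = 3.33e-06; 15 of 17 below 0, 1 lower adjusted over the list alone), as were stem cell genes (0.0296), keratins and junctions (0.0136; 1 lower adjusted over the list alone) and cholesterol synthesis (0.000584; 2 lower adjusted over the list alone). Giant cells (0.0266; 2 higher adjusted over the list alone), steroid synthesis (0.0175; 2) and mesenchyme (0.000885; 3) were higher. For these 7 lists the adjusted p = 0.262 to 0.377 with an estimated correlation, and giant cells had 0.0663 with the line as replicate block. Median centring moved the median change of all genes to -0.27.

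The Rosi response differed between days in 1 gene, Hrh3 (adjusted p = 0.0406; 157 at an unadjusted p under 0.05), and in 0 with the line as replicate block. Of the 25 lists 1 passed for this response with the preset correlation, also with the line as replicate block, and 0 with an estimated correlation. The null-against-WT difference with Rosi differed between days in 4 genes (392 at an unadjusted p under 0.05): Hrh3, whose difference was higher at day 4, and Fcmr, the aminoacylase Acy1 and the ephrin receptor Ephb4, whose differences were lower. No size is given, since each has a day 4 group under the filter limit. Ephb4 went from 404 ± 65.1 in WT to 23.8 ± 5.09 in null lines at day 4 and from 389 ± 52.7 to 148 ± 6.93 at day 2. Median centring moved the median of this difference over all genes to -0.29. The 4 became 0 with the line as replicate block, 37 and 19 without day 4 null replicates 1 and 2, and 0 to 3 without any other 1 array. For the Rosi response the count was 1 without day 4 untreated replicate 1, 2 without day 4 Rosi replicate 3 and 0 without any other 1 array. Cholesterol synthesis was higher in the null difference at day 4 than at day 2 (adjusted p = 0.0264; adjusted p = 0.595 with an estimated correlation; 0 of 15 called on both counts), with adjusted p = 0.0664 with the line as replicate block.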

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

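The heterogeneity test of the decidual markers, the set tests of Rosi at day 2, the regrouping test of differences between mutants, the extension of the placental splits from those that part every litter pair to all 10 and the readings of the Ncoa6 scaling test and of the heterogeneity test were chosen only after results had been seen.

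The 3 genes called with Med1 in Med1-null placentas, Smarce1, Taf15 and Mettl16, all lie on chromosome 11, where 0.250 of 3 would lie by chance (Fisher's exact test, p = 0.00058). Among genes that were not called, those with an unadjusted p under 0.01 lay on chromosome 11 more often than the others (57 of 445 where 37.0 would by chance; odds ratio 1.65, 95% interval 1.22 to 2.21, Fisher's exact p = 0.00113), which fits a chromosome segment inherited with the targeted allele. Other probe sets of Smarce1 and Taf15 above the filter had a median change of -0.0652: that of Smarce1 was flat and that of Taf15 was lower in every pair (-0.38 to -0.01), while Mettl16 has no other above it. Sequence variants under the probes may therefore bear on Smarce1 and are open for the others. Between Med1 and these genes lie 19, 135 and 245 of the 1025 tested genes of the chromosome, and the strains of the alleles are not given.

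In the Rxra cohort Y-linked signal was near the floor in the 3 WT pools and present in the 3 null pools, so sex and genotype could be confounded. With the Y-linked signal as a covariate the changes of the called genes kept their size (median ratio 1.01, quartiles 0.939 to 1.07), and all 197 kept their sign, which argues against sex composition as the source of the changes. The slope of that covariate comes from all 4 cohorts, and 86 of the 197 genes stayed called. Of the called genes 5.05% lay on X or Y against 3.33% of the tested genes (10 of 198; odds ratio 1.56, 95% interval 0.728 to 2.96, Fisher's exact p = 0.163), which leaves a share of sex-linked calls open. The sex of the pools is not given.

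In Ncoa6-null placentas decidual markers were lower and more genes were lower than higher. The 9 markers ranged from -1.66 to -0.22 and differed beyond their errors (Cochran's Q against a chi-square distribution, p = 2.07e-14, too small since it takes the errors as known and the markers as independent). A marker that is also expressed in the placenta would fall by less under the same loss of maternal tissue, and no such baseline was measured, so a loss of maternal tissue stays open. The share of lower calls was 62.7% and 58.6% after quantile normalization, which meets the bound of 10 points written before. Centring each array on its median gave 52.3%, beyond that bound, so a bound on quantile normalization alone was too narrow, and after these values were seen scaling was left open.

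Regrouping the arrays gave 10 splits of 3 against 3 for each placental comparison, the real split included, so a share under 0.05 cannot be reached. As many genes were called in 1 split for Pparg-null (358, highest other 24), in 1 for Rxra-null (198, highest other 2), in 3 for Med1-null (4, highest other 13) and in 1 for Ncoa6-null placentas (1818, highest other 7). For Rosi at day 2 it was 10 splits (0, highest other 0), for Rosi at day 4 it was 3 (1, highest other 2) and for day 4 against day 2 in untreated lines it was 10 (0, highest other 0). The splits of TSC were fitted without the line block, though the WT lines pair by number. With that block genes were called for day 4 against day 2, so its splits decide nothing. For the Rosi response between days, 6 of 100 splits gave as many (1, highest other 3), so that count could arise from how the lines happen to fall into groups.

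The changes of 6 litter pairs, 3 of each mutant, were regrouped in 10 splits for differences between mutants, where again a share under 0.05 cannot be reached. As many genes differed in 1 split for Rxra (3, highest other 0), in 1 for Med1 (101, highest other 0) and in 1 for Ncoa6 (598, highest other 0). For Rxra the 3 genes are Dcaf12l1 and the targeted Pparg and Rxra. The targeted genes differ by design, so for Rxra the lead of the real split says little about other genes. The regrouping replaced a first test, run before it, that exchanged null and WT within pairs. There as many genes differed in 6, 2 and 3 of 32 splits, with 777, 171 and 1677 in the highest other split. In each case that was the split that exchanged every pair of 1 mutant, which tests the sum of 2 real changes and not their difference. Without the replicate block the counts were 10, 106 and 552.

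Fitted log2 differences are given here as what the model returned. Those of Pparg, Hrh3, Acy1, Ephb4 and Fcmr rest on a group with signals under the filter limit, so they depend on the pseudocount and do not measure a size. Between Pparg-null and Rxra-null placentas 3 genes differed, with fitted differences of -1.67 for Dcaf12l1, -7.76 for Pparg and 0.96 for Rxra. Between Pparg-null and Med1-null placentas 101 genes differed, and between Pparg-null and Ncoa6-null placentas 598. The Rosi response differed between days in 1 gene, Hrh3, with a fitted difference of -3.29. The null-against-WT difference with Rosi differed between days in 4 genes, with fitted differences of -2.96 for Acy1, -2.65 for Ephb4, -3.16 for Fcmr and 3.93 for Hrh3. Rosi-treated WT arrays enter both Hrh3 differences with opposite sign, so these are not independent.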

How the results depend on the processing

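All alternatives named as added, and the omission of arrays for differences between mutants or days, were chosen only after results had been seen. Of 274 alternative values of the main results 140 stayed within 1.5 times the main value and 134 moved. No named gene called in a comparison reversed (0), but many calls were lost. Apart from the 2-fold minimum and the omission of single replicates, some setting lost 40 of 40 in Pparg-null, 30 of 30 in Rxra-null, 4 of 4 in Med1-null and 35 of 84 in Ncoa6-null placentas, and 35 of 38 in null TSC at day 4. Leaving out 1 replicate or another lost 22 of the 40, 18 of the 30, 2 of the 4 and 28 of the 84 placental calls. The 2-fold minimum lost 42 of the 84 in Ncoa6-null placentas. All values below are numbers of genes called, "P-R", "P-M" and "P-N" are differences of Pparg-null from Rxra-null, Med1-null and Ncoa6-null placentas, and apart from what the construction of a setting shows the cause was not tested. Leaving 1 array out of the 2 null TSC lines leaves a lone sample, which is then assumed to vary like the other groups. Signal over background limits what arrays can show for weakly expressed genes.

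With no filter the counts were 170 in Pparg-null, 106 in Rxra-null and 1183 in Ncoa6-null placentas, 19 for P-M, 202 for P-N, 2 for Rosi at day 4, 13 for null against WT with Rosi at day 2, 121 for null against untreated WT at day 4 and 0 for the Rosi response between days. With the mean above the 60th percentile of all probe sets they were 9 for P-R, 186 for P-M, 0 for Rosi at day 4, 40 for null against WT with Rosi at day 2, 1 for day 4 against day 2, 0 for the Rosi response and 2 for the null difference between days. With the mean of all probe sets of a gene they were 230 in Pparg-null, 125 in Rxra-null and 2 in Med1-null placentas, 31 for P-M, 356 for P-N and 2 for Rosi at day 4.

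Quantile normalization gave 8 in Med1-null placentas and 0 for the Rosi response between days. Centring each array on its median gave 131 in Rxra-null placentas, 1 for P-R and 50 for P-M. A pseudocount of 32, which was added, gave 13 in Med1-null placentas, 6 for P-R, 165 for P-M, 0 for Rosi at day 4, 1 for day 4 against day 2, 0 for the Rosi response and 0 for the null difference between days. With trend and robust eBayes the counts were 573 in Pparg-null, 323 in Rxra-null and 22 in Med1-null placentas, 13 for P-R, 232 for P-M, 906 for P-N, 0 for Rosi at day 4, 0 for the Rosi response and 0 for the null difference between days.

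A change of at least 2-fold, which by construction keeps only part of the calls, left 73 in Pparg-null, 52 in Rxra-null and 320 in Ncoa6-null placentas, 43 for P-M, 212 for P-N and 10 in the overlap of placentas and TSC (49 without it). Without the replicate block there were 11 in Med1-null placentas and 10 for P-R. With only the 6 arrays of a comparison, and so fewer degrees of freedom, there were 0 in Pparg-null, 0 in Rxra-null, 0 in Med1-null and 592 in Ncoa6-null placentas. With only the arrays of the 2 groups there were 0 for Rosi at day 4, 2 and 9 for null against WT with Rosi at days 2 and 4, and 5 and 2 for null against untreated WT at days 2 and 4. The Y-linked signal as covariate, which was added, gave 175 in Pparg-null, 101 in Rxra-null and 8 in Med1-null placentas.

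With the line as replicate block (a fixed block) there were 156 for day 4 against day 2, 98 higher and 58 lower, 0 for Rosi at day 4, 0 for the Rosi response and 0 for the null difference between days. With trend and robust eBayes added to that block there were 685 (361 higher and 324 lower), 19, 0 and 2. With the line as a random block there were 82 for day 4 against day 2 and 11 for the null difference between days. Leaving out WT line 3, which was added, gave 15 for null against untreated WT at day 2, 0 for Rosi at day 4, 0 for the Rosi response and 0 for the null difference between days. Of the 63 list tests called with a preset correlation 0 were called with an estimated correlation.

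Leaving out 1 replicate or array gave from 148 to 254 in Pparg-null, 52 to 59 in Rxra-null, 3 to 12 in Med1-null and 777 to 1009 in Ncoa6-null placentas. It gave 1 to 5 for P-R, 19 to 75 for P-M and 193 to 428 for P-N. In TSC it gave 0 to 0 for Rosi at day 2, 0 to 2 for Rosi at day 4, 9 to 22 and 255 to 547 for null against WT with Rosi at days 2 and 4, 4 to 17 and 79 to 387 for null against untreated WT at days 2 and 4, 0 to 0 for day 4 against day 2, 0 to 2 for the Rosi response and 0 to 37 for the null difference between days.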

Other observations

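The set tests of Rosi at day 2 weighed here, and the adjustment of those with the line block, were chosen only after results had been seen.

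Genes higher in Pparg-null placentas were also higher as a set in Rxra-null placentas (125 of 146 above 0, median 0.33; adjusted p = 5.10e-05 with an estimated correlation) and in null TSC at day 4 (92 of 136 above 0, median 0.44; adjusted p = 0.0254 with an estimated correlation). In Ncoa6-null placentas 79 of 146 were above 0 (adjusted p = 0.0824 with an estimated correlation). Genes lower in Pparg-null placentas had 152 of 202 below 0 in null TSC at day 4 (median -0.50; adjusted p = 0.0666 with an estimated correlation). The family held 34 set tests.

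Genes higher in null TSC at day 4 were lower as a set in WT TSC given Rosi at day 2, a comparison that shares no array with the one that chose them but uses the same 3 WT lines. Of these 96 of 128 were below 0 (median -0.17; adjusted p = 0.0231 with the line block and an estimated correlation, unadjusted 0.00315, and adjusted p = 0.0012 without the block). Of the genes lower in null TSC 288 of 346 were above 0 (median 0.20), but this set did not pass at either setting (adjusted p = 0.0999 with the line block and an estimated correlation, unadjusted 0.0454, and adjusted p = 0.0632 without the block). Nor did the sets chosen in placentas, which share no line with the TSC. For Rosi at days 2 and 4, 140 and 138 of 202 genes lower in Pparg-null placentas were above 0 (adjusted p = 0.324 and 0.119 with an estimated correlation), and 85 and 92 of 136 higher ones were below 0 (0.0754 and 0.0793). The test of the higher genes from TSC is consistent with a response of receptor-dependent genes to the agonist, though 0 genes were called singly at day 2. The other sets leave it open, and differences between sets were not tested. With 3 lines, and 0 genes called with the line as replicate block (the fixed block) at either day, it may also rest on a shared state of the cultures, such as their pace of differentiation, which was not measured apart from treatment.

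Within a day the Rosi and null comparisons share the WT Rosi arrays, which by itself makes their changes covary with opposite sign. With the sign of the null change reversed, the covariance at day 2 across genes, which are not independent, was 0.0825, and at most 0.110 in simulations with shared arrays only. At day 4 it was 0.153, against a highest simulated value of 0.109, while the correlation was within the simulations (r = 0.423, highest simulated 0.474). Across days, with no shared array, it was 0.0522 and 0.0498, with highest simulated values of 0.00860 and 0.00665. The simulations hold no correlation between arrays of 1 line, which was 0.483 in the data, so these values are not shown to exceed what shared lines give.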
